A study of Hordeum vulgare with 18 samples.

How the data were processed

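Shoots and roots of barley seedlings were profiled on Agilent 2-colour arrays of 43900 spots, of which 42483 hold distinct 60-base probes and 1417 are control spots. Per the labels' protocols, 7 seeds per dish germinated in 4.5 mL water at 24 °C for 4 days with an 8 h day, 3 germinated seeds were moved to dishes with 4.5 mL of ABA solution, RNA was extracted with Trizol, and 400 ng was labelled with the Quick Amp kit. The labels give the ABA concentration as 50 mM, where micromolar concentrations are usual, and this value could not be checked here. On every array Cy3 holds untreated 0 h RNA and Cy5 holds RNA of ABA-treated tissue, so a positive log2 ratio means higher after treatment. Tissue, time and replicate number were taken from the sample labels.

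The deposited scanner files hold spot and background intensity in both channels, made with Agilent Feature Extraction, version 9.1 per the submitters' processing notes and 9.5 or 9.1 per the file headers. The deposited processed intensity values were background-subtracted, spatially detrended and dye-normalized by that program, per the file headers. The authors deposited a series table of log10 ratios, red over green. Each column equalled the log10 ratio of the array's scanner file on 100% of spots, so its scale, centring and direction are those of the program. Array medians of that table lay between -0.0202 and 0 on the log10 scale.

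From the mean spot signals and median local backgrounds, background was corrected by normexp with an offset of 50, each array was normalized by loess, and control and outlier-marked spots were left out, with R 4.3.3 and limma 3.58.1. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. Probes well above background in at least 1 channel on at least 3 of the 4 arrays of at least 1 group were kept, 39055 of 42483. One limma model of the 16 arrays at 3 h and 6 h, with the 4 groups as terms, gave each group's log2 ratio against 0 and the differences between times and between tissues, all 2-sided. A probe was called at a Benjamini-Hochberg adjusted p under 0.05, adjusted over the 39055 probes of each comparison. The at least 2-fold counts add a log2 change of 1 or more. The 2 arrays at 24 h entered no test. Since all arrays had the same dye orientation, a dye effect specific to a probe stays in the ratios against 0 h and cancels in the differences. A probe not well above background at 0 h on every array of a group has only a lower bound on its rise. That bound sets the treated mean against the higher, per array, of the lowest signal among detected probes and its own signal, after loess and Aquantile, and is open to dye bias.

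Named probes were chosen by a rule set before the data were examined. Without gene names it takes, per comparison, at most 2 probes that rose and 2 that fell, with the largest changes among those called. For the ratios these also needed 1 sign on all 4 arrays and a signal well above background in at least 1 channel on each. At 24 h the rule is size alone. None of the probes' clone identifiers (0) was found among the 58438 genes of the reference table (assembly MorexV3), so 27 gene lists set beforehand, on hormone, stress, clock and growth genes, could not be tested, and neither could a test of clock genes at 24 h. Pairs of named probes that share at least 30 bases are stated where named.

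Overlaps between comparisons were set beside n1 × n2 / N for independent lists. Because arrays of one replicate number might share 0 h RNA, correlation and covariance of group means were also computed from array deviations alone, with the sign of each replicate number's deviations turned in 7 ways. The replicate numbers pair the samples: deviations from the group mean correlated at 0.146 to 0.839 in all 24 pairs of arrays of one number, against a median of -0.21 for other pairs. The arrays lay on 5 slides, read on 2 scanners. Replicates 2, 3 and 4 filled 1 slide each with all 4 groups, while the 6 h arrays of replicate 1 and its 3 h and 24 h arrays lay on separate slides. Within a slide each group had 1 array, so no test within a slide was possible.

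The fit was tested on simulated arrays with 200 changed probes among 39055. For ratios against 0 h it recovered 82% (shoot 3 h), 84% (shoot 6 h) and 82% (root 3 h) of 2-fold changes, and 62% for root 6 h against 3 h and 60% for root against shoot at 6 h. False calls numbered 6 to 12 per ratio comparison and were 0 when no probe was changed. The simulated noise was independent between probes, and part of its variance was shared by arrays of one replicate number. The real arrays share structure between probes and gave far more calls, so these false-call counts need not hold for them. Alternatives were no background correction, Agilent's processed signals, the deposited table, median centring, other filters on dim probes, another variance prior, groups fitted alone, blocks for replicate or slide, and leaving out each replicate. The fits that left out a replicate had no block. These 4 were added after the data were seen: scaling between arrays, a replicate block within each tissue, slide as a fixed block, and leaving out the 3 h arrays of replicate 1.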

Results

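The expression of barley (Hordeum vulgare, cultivar Haruna Nijo, a malting barley) was measured in shoots and roots of germinated seeds given abscisic acid (ABA), the plant hormone of water deficit and seed dormancy. Seeds germinated for 4 days in water were moved to dishes with ABA, at 50 mM per the labels, and shoots and roots were harvested separately. Each array compared treated tissue, in Cy5, with untreated 0 h tissue of the same kind, in Cy3. Shoot and root at 3 h and at 6 h had 4 arrays each, described in the labels as biological replicates, and shoot and root at 24 h had 1 array each analysed here. The p-values measure the spread between these samples, and the number of arrays limits the precision. Median spot brightness ranged from 495 to 1232 in Cy3 and from 876 to 2149 in Cy5 over the 18 arrays, against local backgrounds of at most 70 and 62.5. Between 84.9% and 90.3% of the probes were well above background in Cy5. No mock-treated or untreated array at 3, 6 or 24 h was analysed here, so a ratio holds the effects of ABA, transfer and elapsed time together, and no array had its dyes swapped. The probes carry cDNA clone identifiers that the files do not pair with genes, so probes are named by clone, with the probe sequence for some. No genome position or gene function is given, apart from protein motifs read from the sequences of a few probes.

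In shoots at 3 h, the probes that rose furthest on all 4 arrays were Hv2079L23_1 and Hv3058L19_1. Hv2079L23_1 (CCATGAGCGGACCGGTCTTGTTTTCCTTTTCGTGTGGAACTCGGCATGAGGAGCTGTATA) rose 54.0-fold, a log2 ratio of 5.76 ± 0.40 (SD, n = 4) with a limma adjusted p of 1.19e-07. Hv3058L19_1 rose by a log2 ratio of 5.66 ± 0.44 (SD, n = 4). Both also rose in root at 3 h, by 3.13 ± 0.71 and 1.78 ± 0.78, and less than in shoot, with differences of -2.62 (SE 0.54, adjusted p = 0.00174) and -3.88 (SE 0.49, adjusted p = 7.08e-05). The furthest falls were those of Hv2051I23_1, at -2.96 ± 1.08, and Hv2097D13_2, at -2.90 ± 0.63. Hv2051I23_1 fell in root as well, at -2.52 ± 0.25, a difference from shoot that did not pass the test (0.44, SE 0.56, adjusted p = 0.556). Hv2097D13_2 was not well above background in Cy5 on any root array at 3 h.

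Of 39055 probes tested in shoot at 3 h, 12449 (31.9%) passed an adjusted p of 0.05, with 6718 higher and 5731 lower than at 0 h (54.0% higher, against 44.7% with Agilent's processed signals). At least 2-fold changes were fewer, 1491 higher and 439 lower, and 109 probes were at least 8-fold higher with 0 at least 8-fold lower. The count of 12449 was 7565 without replicate 1 and 5365 when the group was fitted alone. Fitted alone, Hv2079L23_1 and Hv2051I23_1 kept their calls, at limma adjusted p of 0.000815 and 0.0166. The count of at least 2-fold changes, 1930, became 2984 with Agilent's processed signals and 3119 with arrays scaled to a common spread, where Hv2079L23_1 read 7.28, Hv3058L19_1 7.16, Hv2051I23_1 -3.79 and Hv2097D13_2 -3.63.

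In shoots at 6 h the furthest rises were those of Hv2083E12_1 (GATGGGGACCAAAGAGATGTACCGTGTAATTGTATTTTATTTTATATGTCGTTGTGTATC), at 5.91 ± 2.64 (SD, n = 4; adjusted p = 0.00239), and Hv1054H21_1, which rose 48.5-fold (SD 1.34 in log2; adjusted p = 0.00146). For Hv1054H21_1, 1 Cy5 spot was saturated, so the ratio of that array may be understated. Both lay higher in replicates 1 and 4 than in 2 and 3: Hv2083E12_1 read 9.63, 4.46, 3.68 and 5.88 in replicates 1 to 4, and Hv1054H21_1 read 7.22, 4.86, 4.20 and 6.13. Hv3091D19_1 fell to -3.59 ± 1.30 and Hv1002K12_1 to -3.49 ± 1.44. Hv1002K12_1 also fell in root at 6 h, to -2.39 ± 0.48 (adjusted p = 0.00653). The leading probes of 3 h stayed high at 6 h, Hv2079L23_1 at 5.56 ± 0.47 and Hv3058L19_1 at 5.29 ± 0.53 on the 3 arrays that measured it.

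In all, 16820 probes (43.1%) were called in shoot at 6 h, 8831 higher and 7989 lower (52.5% higher, against 48.7% with Agilent's processed signals), and 3222 of them changed at least 2-fold, 1893 upward and 1329 downward. Median centring without loess moved the share of higher probes among the at least 2-fold changes from 58.8% to 70.6%. With the scaled arrays Hv2083E12_1 read 6.59 and Hv1054H21_1 6.32.

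In roots at 3 h Hv2115D22_1 (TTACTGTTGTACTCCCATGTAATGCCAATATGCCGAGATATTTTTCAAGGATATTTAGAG) rose 300.3-fold, a log2 ratio of 8.23 ± 0.89 (SD, n = 4; adjusted p = 4.51e-08). Hv2004D15_1 (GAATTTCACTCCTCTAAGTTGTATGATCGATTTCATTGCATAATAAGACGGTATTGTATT) rose 161.5-fold, at 7.33 ± 0.43 (adjusted p = 2.27e-09). Hv1090G12_1 (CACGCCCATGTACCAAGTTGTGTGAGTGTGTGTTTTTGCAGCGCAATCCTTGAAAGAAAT) fell to -4.64 ± 1.18 (adjusted p = 3.39e-06), and Hv2009P09_1 to -4.52 ± 0.52, or 23.0-fold (adjusted p = 4.4e-07). In shoot, Hv1090G12_1 had a log2 ratio of 0.42 ± 1.18 that did not pass the test (adjusted p = 0.588).

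In root at 3 h, 24351 probes (62.4%) were called, 12550 higher and 11801 lower (51.5% higher, against 43.5% with Agilent's processed signals). Replicate 3 stood apart for some strongly higher probes: of 409 with a log2 ratio over 3 in replicates 1, 2 and 4, 93 were more than 8-fold lower in replicate 3, with a median log2 Cy3 level at 0 h of 11.29 against 6.84 to 7.61. Of the called probes, 4472 were at least 2-fold higher and 2541 at least 2-fold lower, and 578 were at least 8-fold higher against 39 at least 8-fold lower. Scaling the arrays to a common spread reduced the 7013 at least 2-fold changes to 4559, and with Agilent's processed signals 52.5% of them were higher against 63.8% here. The sizes of the named changes also depended on the processing: Hv2115D22_1 read 6.36 with scaled arrays and 9.14 with Agilent's processed signals, Hv2004D15_1 5.69 and 7.97, and with scaled arrays Hv1090G12_1 read -3.65 and Hv2009P09_1 -3.50.

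In root at 6 h Hv2115D22_1 was still the highest of the eligible probes, at 6.76 ± 1.07 (SD, n = 4; adjusted p = 3.44e-07), and its difference from 3 h, -1.47 (SE 0.84), did not pass the test (adjusted p = 0.494). Hv2146A12_1 rose by 6.55 ± 1.58 (adjusted p = 1.25e-06), with 4.76 in replicate 3 and 5.70 to 8.10 in the others. Hv1090G12_1 fell by 4.95 on the log2 scale (SD 0.94) and Hv2081M21_1 by 4.66 (SD 0.41; adjusted p = 8.32e-11). Hv2081M21_1 was well above background on all root arrays in both channels and on no shoot array in Cy5 at 3 h and 6 h. Calls numbered 22785 (58.3%), 11693 higher and 11092 lower (51.3% higher, against 47.4% with Agilent's processed signals), with 3542 at least 2-fold higher and 3026 at least 2-fold lower. Of the 6568 at least 2-fold changes 53.9% were higher, against 65.6% with median centring without loess, and 47.7% of 9971 with Agilent's processed signals, where Hv2115D22_1 read 8.38, Hv2146A12_1 7.46 and Hv1090G12_1 -5.64.

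**Figure D1:**
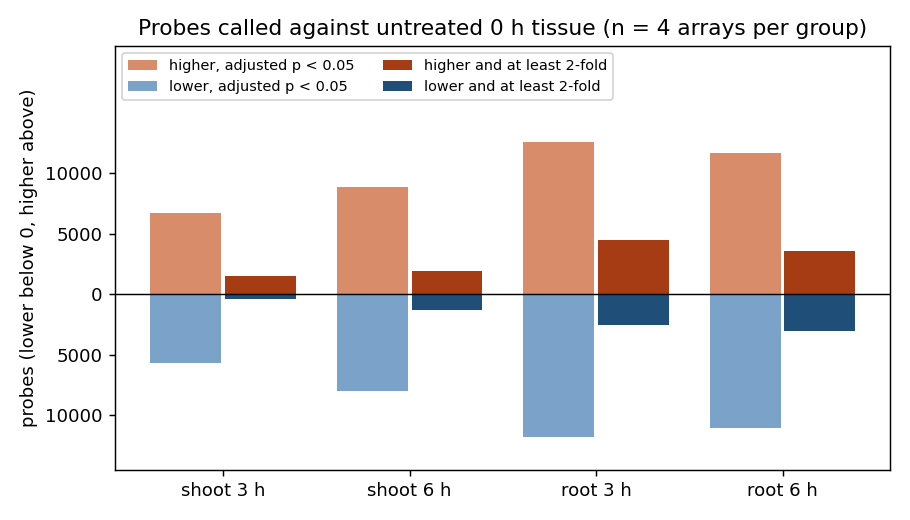
Number of probes called against untreated 0 h tissue (vertical axis, probes; higher above 0, lower below 0) in each tissue and time with 4 arrays. Pale bars count all probes past an adjusted p of 0.05, and dark bars those changed at least 2-fold. Root bars, at 24351 and 22785 probes in all, exceed shoot bars, at 12449 and 16820.

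Between 3 h and 6 h the number of called probes depended on whether the fit used the pairing of the arrays by replicate number. In shoot, Hv2004E19_2 went from 1.75 ± 0.57 at 3 h to 3.87 ± 0.78 at 6 h (SD, n = 4), a difference of 2.12 (SE 0.39, adjusted p = 0.0368), and Hv2110I16_1 rose between the times by 1.99 (SE 0.38, adjusted p = 0.0425). Hv1028P07_1 went from -0.31 ± 0.48 to -2.66 ± 0.77 (difference -2.35, adjusted p = 0.00658) and Hv3007F02_1 from -0.59 ± 0.06 to -2.47 ± 0.49 (difference -1.88, adjusted p = 0.00284). Hv1028P07_1 was not well above background on any root array in either channel. In all, 140 probes were called, 49 higher and 91 lower at 6 h, and 3942 had an unadjusted p under 0.05. The fit with the replicate number as a block called 791, and with a block within each tissue, added after the data were seen, 2808, with 47.7% and 45.4% higher against 35% of the 140. The direction of the 140 depended on the processing: 78.6% of 28 calls were higher with Agilent's processed signals, 71.9% of 32 with the deposited table, 64.7% of 17 with the strict filter and 52.8% of 36 with median centring. Without any 1 replicate the count, in fits without the block, fell to between 4 and 10. The calls of Hv2004E19_2 and Hv2110I16_1 did not pass with slide as a fixed block (differences of 2.07 and 1.94, adjusted p = 0.0584 and 0.0708) or when any 1 replicate was left out. Neither did that of Hv1028P07_1 when any 1 replicate was left out (adjusted p from 0.0576 to 0.118), nor that of Hv3007F02_1 without replicate 1 or 4 (0.0789 and 0.0905). With shoot at 3 h and 6 h fitted alone 0 probes were called, so the calls of all these named probes were lost there as well.

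In root, the probes with the largest called drops moved back toward their 0 h level. Hv2078F04_1 (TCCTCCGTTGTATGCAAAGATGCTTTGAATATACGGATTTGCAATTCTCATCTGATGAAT) dropped from 4.28 ± 0.59 at 3 h to 1.48 ± 0.67 at 6 h (SD, n = 4), a difference of -2.80 (SE 0.32, adjusted p = 0.00374). Hv2011N24_1, which shares 50 bases with it, dropped from 4.56 ± 0.58 to 1.82 ± 0.60. On the single 24 h root array these probes read -0.63 and -0.50. Hv2003H23_1 went from 1.62 ± 0.31 to 2.76 ± 0.46 (difference 1.14, adjusted p = 0.0455), and Hv3024F12_2 from -0.29 ± 0.16 to 0.77 ± 0.35 (difference 1.05, adjusted p = 0.0461). On the single 24 h root array they read -2.54 and 1.18. The count was 243, 63 higher and 180 lower at 6 h, with 5191 at an unadjusted p under 0.05, and 2270 with the replicate number as a block (4842 with a block within each tissue). In fits without the block, the count of 243 fell to 0 without replicate 1 and to 0 without replicate 3. With median centring without loess 64.6% of 347 calls were higher, against 25.9% here. The calls of Hv2078F04_1 and Hv2011N24_1 did not pass without replicate 1 (adjusted p = 0.104 each) or replicate 3 (0.205 each), and that of Hv2011N24_1 also not without replicate 4 (0.0634). With scaled arrays their differences were -2.03 and -1.93. That of Hv2003H23_1 did not pass without replicate 1, 3 or 4, and that of Hv3024F12_2 when any 1 replicate was left out.

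The response of root was set against that of shoot by the difference of their log2 ratios, in which a constant dye effect cancels. At 3 h Hv2004D15_1 was 6.19 higher in root than in shoot (SE 0.55, adjusted p = 3.41e-06) and Hv2004D15_2, a probe of the same clone sharing 50 bases, 6.18 higher by the fit. The 0 h signal of Hv2004D15_2 in shoot was well above background on 0 of 4 arrays, so its shoot rise is only bounded, at 1.90-fold or more, and the difference is not exact. The 0 h signal of Hv2004D15_1 in shoot was well above background on 1 of 4 arrays at 3 h, so that its difference is not exact either, and on 0 of 4 at 6 h, where its rise was at least 3.29-fold. With Agilent's processed signals these differences were 4.05 and 3.92, and with scaled arrays 4.18 and 4.27. Hv2098D06_1 was lower in root, by a difference of -5.18 (SE 0.89, adjusted p = 0.000513): it fell in root, at -3.79 ± 0.82 (SD, n = 4), and read 1.39 ± 1.92 in shoot. Its shoot arrays read 3.14 and 2.95 in replicates 1 and 4 and -0.08 and -0.45 in 2 and 3. Hv1090G12_1 was lower in root as well, with differences of -5.06 at 3 h and -5.19 at 6 h. At 6 h Hv2146B09_1 was higher in root by 5.39 (SE 1.19, adjusted p = 0.00282), and so was Hv2013O22_1, which shares 50 bases with it, by 5.37. In replicate 3 these probes read 3.17 and 3.08 in root, below the other replicates (6.10 to 7.96). Both calls were lost without replicate 4 (adjusted p = 0.0509 and 0.0548). Hv2083E12_1 was lower in root, with a difference of -5.05 (SE 1.88, adjusted p = 0.0476), a call lost when any 1 replicate was left out. Differences were called for 15068 probes at 3 h, 8105 of them higher in root, and for 14636 at 6 h, 7407 of them higher in root. With Agilent's processed signals the share higher in root was 47.0% at 3 h, against 53.8%, and 46.5% at 6 h, against 50.6%. Leaving out replicate 3 or replicate 4 reduced the count at 6 h to 9236 and 9400. Among called differences of at least 2-fold, 2646 were higher and 2129 lower in root at 3 h. At 6 h the majority was the other way, with 2242 higher and 2478 lower in root.

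On these arrays the log2 ratios were spread more widely over the probes in root than in shoot. The SD per array was 1.00 ± 0.10 (n = 4) in root against 0.63 ± 0.11 in shoot at 3 h, and 0.95 ± 0.09 against 0.69 ± 0.05 at 6 h. Each difference had a 2-sided exact permutation p of 0.0286, the smallest that 4 against 4 arrays can give, and 0.0571 after adjustment over 4 such tests, which is not under 0.05. The permutation ignored the pairing by replicate number, and exchanges within 4 pairs are too few for a p under 0.05. The 6 h and 3 h arrays did not differ detectably, with exact p of 0.343 in shoot and 0.457 in root.

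Many probes moved the same way in both tissues. Hv2051I23_1 fell and Hv2115D22_1 rose in both tissues at both times, Hv2115D22_1 by 2.69 ± 2.05 in shoot at 3 h and 3.34 ± 0.79 at 6 h (SD, n = 4). At 3 h 4738 probes were called higher in both tissues, where independent lists would share 2159, and 3385 were called lower in both, against 1732. Opposite calls numbered 853, against 3872 for independent lists. The difference itself was called for all 853, which follows from calls of opposite sign in the same fit and adds no support. At 6 h the counts were 5665 higher, 4176 lower and 1366 opposite, with a called difference for all 1366 for the same reason. Over the probes, which are not independent replicates, the tissue means had a covariance of 0.274 at 3 h and 0.305 at 6 h, against 0.0193 and 0.00997 with the array deviations alone. Their correlation was 0.561 and 0.545, against means of 0.373 and 0.286 (highest 0.4996 and 0.366) with the deviations alone. A dye effect specific to a probe would also give the same sign in both tissues. Neither the independent lists nor the deviations remove it. Without replicate 1 the 8123 probes called in the same direction at 3 h became 5055, and without replicate 3 the 9841 at 6 h became 6461.

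The means at 3 h and 6 h had a covariance of 0.302 in shoot and 0.773 in root, against 0.0263 and 0.0300 with the array deviations alone, and 0.275 and 0.740 when the times were taken from different replicate numbers. The correlations were 0.914 and 0.937, against 0.755 and 0.588 (highest 0.863 and 0.800) with the deviations alone. A dye effect specific to a probe would also be shared by the times, and these comparisons do not remove it. Hv2115D22_1, Hv2004D15_1 and Hv1090G12_1 kept their direction in root at both times. Probes called higher at both times numbered 5723 in shoot and 10153 in root, and probes called lower 4877 and 9486, with 17 and 47 called in opposite directions, of which 8 and 23 had a called difference.

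**Figure D2:**
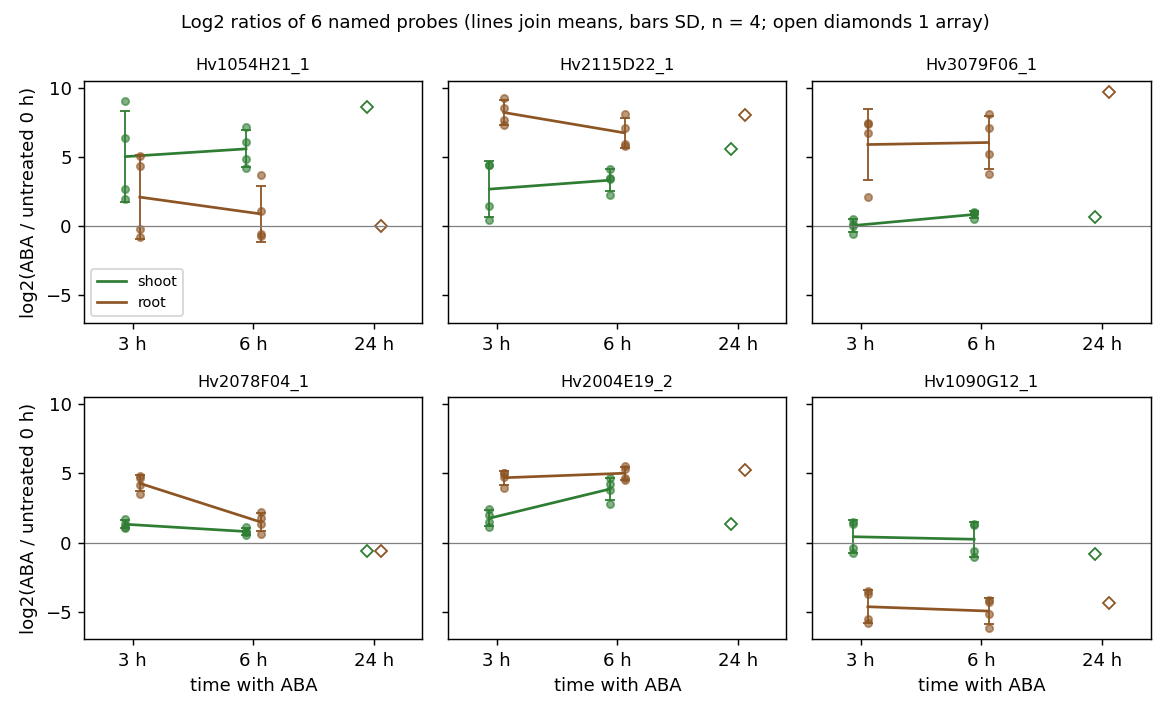
Log2 ratio of treated over untreated 0 h tissue (vertical axis) against time with ABA (horizontal axis) for 6 named probes in shoot (green) and root (brown). Points are arrays, lines join the means, bars are SD over 4 arrays, and open diamonds are single 24 h arrays. The 24 h arrays are of replicate 1, which read highest for Hv1054H21_1 in shoot at 3 h and 6 h. Hv1090G12_1 fell in root, at -4.64 and -4.95, while Hv2078F04_1 dropped in root from 4.28 to 1.48. In shoot Hv1090G12_1 had means near 0, with replicates 1 and 4 above 0 and 2 and 3 below at both times.

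At 24 h each tissue had 1 array, so these are values with no replicate check and no p-value, and the spike-in spots of these arrays correlated less well with their set ratios (0.800 in shoot, 0.799 in root) than on the 3 slides of replicates 2 to 4. The highest ratios in shoot were those of Hv1054H21_1, at 8.62, and Hv2083E12_1, at 8.43, the probes that also led at 6 h. The 24 h array is of replicate 1, which read highest for both probes at 3 h and 6 h. There Hv1054H21_1 read 9.07 and 7.22 and Hv2083E12_1 9.22 and 9.63, so the 24 h values show no clear further rise. The lowest were those of Hv2013L05_1, at -3.54, and Hv2072I18_1, at -3.50. Hv2072I18_1, which also read far lower in replicate 1 than in the others at 3 h and 6 h, read -6.58 at 24 h with Agilent's processed signals. In root Hv3079F06_1 (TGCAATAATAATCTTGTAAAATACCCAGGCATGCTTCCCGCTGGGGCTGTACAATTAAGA) read 9.71, or 836-fold, and Hv3079F06_2, sharing 50 bases with it, 9.66, against 0.69 and 0.66 in shoot. At 3 h in root they read 2.09 and 2.11 in replicate 3 and 6.73 to 7.48 in the others. Scaling the arrays to a common spread gave 7.63 and 7.59 for them at 24 h, 11.14 for Hv1054H21_1 in shoot and -4.73 for Hv2081M21_1 in root. Hv2130H01_1 read -6.21 and Hv2081M21_1 -6.02 in root. At least 2-fold ratios numbered 2870 in shoot, 1795 higher and 1075 lower, and 7976 in root, 3771 higher and 4205 lower. The shoot count depended on the processing and reached 7318 with median centring without loess.

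Probes called at 6 h with at least 2-fold changes on replicates 2 to 4 were followed over time on the replicate 1 arrays, which took no part in the choice. In shoot, 1624 higher probes had median log2 ratios of 1.64 at 3 h, 1.71 at 6 h and 1.15 at 24 h, and 96.8% were above 0 at 24 h. The 1157 lower probes had medians of -0.91, -1.40 and -0.79. In root, 3437 higher probes had medians of 2.11, 1.53 and 1.30, and 3247 lower probes -1.23, -1.17 and -1.45. The times rest on 1 array each, so their differences were not tested. A dye effect specific to a probe would keep its sign on these arrays too, and choosing on other replicates does not remove it. The replicate 1 arrays might also share 0 h RNA.

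**Figure D3:**
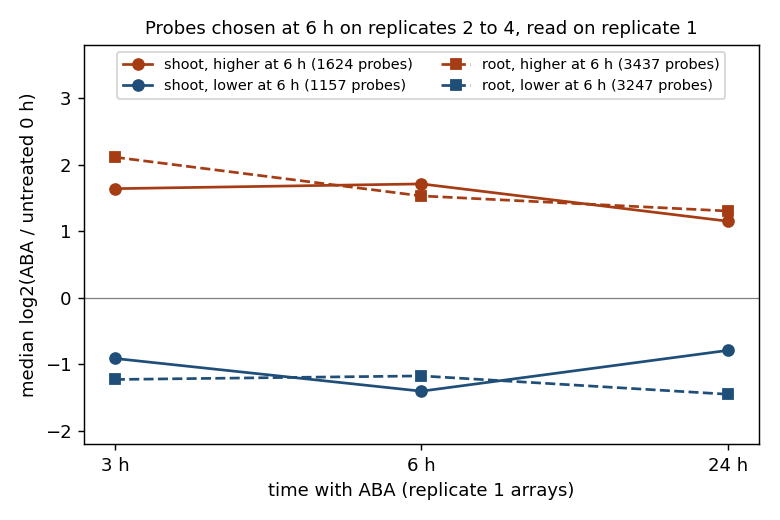
Median log2 ratio (vertical axis) on the replicate 1 arrays against time with ABA (horizontal axis, evenly spaced) for probes called at 6 h on replicates 2 to 4, in shoot (solid lines) and root (dashed lines), higher (red) or lower (blue). All 4 sets stayed on their side of 0 at 24 h, with medians of 1.15 and -0.79 in shoot and 1.30 and -1.45 in root. A dye effect specific to a probe is not removed.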

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

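The tests chosen after the result was seen are those that part the same-direction probes by an F test, those on replicates 1 and 4 against 2 and 3, on a shared 0 h extract, on root replicate 3, and the slide block for root; the F test share and the splits were planned.

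A sample far from the other 3 of its group (by the gap to the nearest relative to the whole range) was found in 16 of 142 groups of values; chance gives about 1 in 20. Among array measures these were the share of probes above background in Cy5 in shoot at 3 h replicate 4 (90.2%, others 88.3% to 88.4%) and the SD of log2 ratios in shoot at 6 h replicate 1 (0.767, others 0.657 to 0.662). The correlation of spike-in spots was low on the 3 h arrays of replicate 1, at 0.795 in shoot (others 0.988 to 0.996) and 0.793 in root (others 0.973 to 0.981), and the 24 h arrays of the same slide read 0.800 and 0.799. Spots marked as outliers by the scanner program numbered 520 in shoot and 449 in root on the 6 h arrays of replicate 1 (others 1 to 11 and 3 to 24), and 6 in shoot at 3 h replicate 2 (others 4).

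Among log2 ratios, root at 3 h replicate 3 lay far below the other replicates for Hv2146A12_1 (3.29, others 7.64 to 8.35), Hv2146B09_1 (2.03, others 7.14 to 7.70), Hv2013O22_1 (1.91, others 7.13 to 7.64), Hv3079F06_1 (2.09, others 6.73 to 7.47) and Hv3079F06_2 (2.11, others 6.79 to 7.48). Of these, Hv2146B09_1 and Hv2013O22_1 share bases, and so do the Hv3079F06 probes. Replicate 1 lay apart in shoot for Hv2072I18_1, at -4.61 at 3 h (others -1.25 to -0.82) and -5.70 at 6 h (others -1.32 to -0.59). Replicate 2 lay apart in root for Hv3007F02_1 at 3 h (-0.58, others -0.01 to 0.04) and for Hv2003H23_1 at 6 h (3.45, others 2.50 to 2.58).

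A difference between groups, each by a limma test of the difference itself, was found between the times for 140 probes in shoot and 243 in root, and between the tissues for 15068 probes at 3 h and 14636 at 6 h. Between the times in shoot the named probes were Hv2004E19_2 (2.12), Hv2110I16_1 (1.99), Hv1028P07_1 (-2.35) and Hv3007F02_1 (-1.88). In root they were Hv2003H23_1 (1.14), Hv3024F12_2 (1.05), Hv2078F04_1 (-2.80) and Hv2011N24_1 (-2.74). Between the tissues they were Hv2004D15_1 (6.19), Hv2004D15_2 (6.18; neither is exact, as their 0 h signals in shoot lie mostly at background), Hv2098D06_1 (-5.18) and Hv1090G12_1 (-5.06) at 3 h, and Hv2146B09_1 (5.39), Hv2013O22_1 (5.37), Hv1090G12_1 (-5.19) and Hv2083E12_1 (-5.05) at 6 h. For the tissues 1 of the 35 splits of the 8 arrays into 4 and 4, the real one, gave as many calls at each time (highest other 187 at 3 h and 8 at 6 h). That share lies under the bound of 0.05 set beforehand. These splits ignore the pairing by replicate number, so chance is not excluded by them. The splits that part every same-number pair as the real one does are 8, too few for a share under 0.05, and the highest other of these gave 0 calls at 3 h and 4 at 6 h by limma.

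The first pattern is that 6316 probes were called in the same direction in all 4 ratios, 3846 higher and 2470 lower, where a dye effect specific to a probe could give the same sign on every array. Of these probes 46.9% passed a limma F test of any difference among the 4 groups, a share between the bounds set beforehand (10% and 50%) and like that of all probes (47.0%), so it does not set these probes apart. For the 2964 that passed, the group means differed past the threshold. This argues against a constant dye effect as the whole cause for them as a set, but not for each probe. For the 3352 that missed, a dye effect and a like response in both tissues cannot be told apart, since no array had its dyes swapped. A response to ABA, transfer or elapsed time stays open and untested for all of them.

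The second pattern is that replicates 1 and 4 resembled each other and differed from replicates 2 and 3, as in Hv1054H21_1 in shoot at 3 h (9.07 and 6.40 against 1.99 and 2.70). For the times, 2 of the 35 splits gave as many calls in shoot (real 140, highest other 4886) and 2 of 35 in root (real 243, highest other 3392); the larger split parts replicates 1 and 4 from 2 and 3 and points to a structure of the samples, so chance is not excluded. The splits that part every same-number pair as the real one does gave at most 0 calls in shoot and 1 in root with the replicate block, against 791 and 2270. With slide as a fixed block 72.7% of the root calls were lower at 6 h. This argues against a slide effect common to both tissues as the whole source of the direction there. That block still uses replicate 1 through its differences between tissues, so a shift of its root arrays alone is not excluded. The scanner is excluded as the whole cause, since replicates 1 and 4, on different scanners, were the closest pair in 4 of 4 groups. Slide and replicate cannot be told apart, since 0 slides hold arrays of more than 1 replicate number. The treated channel parted the replicates alike in 4 of 4 groups. Since deviations of Cy3 and Cy5 on an array went together (r of 0.221 to 0.444 by group), a slide effect could part both channels. The 0 h RNA alone is therefore not excluded as the source in the ratios. One 0 h extract on both arrays could give the deviations shared by 3 h and 6 h arrays, since Cy3 deviations correlated more strongly than Cy5 in 8 of 8 pairs (0.663 to 0.939 against 0.503 to 0.672). Root replicate 1 had the lowest Cy3 correlation, 0.663 against 0.890 to 0.939 in the other pairs, so one extract is least clear for it. Separate 0 h extracts of one batch would give shared deviations too, and no biological explanation was tested.

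The third pattern is that 93 of the 409 probes strongly higher in root at 3 h in replicates 1, 2 and 4 were more than 8-fold lower in replicate 3, against 0 of 219, 17 of 301 and 0 of 228 for the same count in replicates 1, 2 and 4. A weaker response of the treated roots is excluded, as the median Cy5 level of these probes lay -0.11 from the lowest other replicate on the log2 scale. The gap lay in the 0 h RNA, with median log2 Cy3 levels of 11.29 on the 3 h array and 11.24 on the 6 h array (others 6.84 to 7.61 and 7.54 to 9.25), which at a median excess of 2.05 on the 6 h array excludes a fault of the 3 h array alone. The 9.25 was that of the root 6 h array of replicate 1, whose 3 h array read 6.84. In replicate 1 the median ratio of these probes was 6.26 at 3 h and 3.69 at 6 h, with Cy5 levels of 13.37 and 13.07. There the lower ratio at 6 h went mostly with the higher 0 h level. Treated root RNA of 3 h mixed into the 0 h RNA would set 1 ceiling on every ratio and is excluded, as 94 of the 409 probes kept a log2 ratio over 4 in replicate 3. RNA of another source, or 0 h roots of replicate 3 that already had high levels, stay open, and no biological explanation was tested.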

How the results depend on the processing

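The tests chosen after the data were seen are scaling between arrays, the replicate block within each tissue, slide as a fixed block and leaving out the slide 2 arrays (the 3 h arrays of replicate 1).

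Of 244 alternative counts 200 lay within 1.5 times the value reported, while the majority direction of several counts turned (below); of 565 alternative values of named probes 490 kept their call or size, 69 lost their call, 6 moved and 0 changed sign. Signal over background limits the ratios of probes dim at 0 h to lower bounds, and 1 named value had a saturated spot. Aquantile leaves the ratios unchanged, and camera and fry were not run, as no gene list was testable. The causes were not tested, except that fewer samples are left when a replicate is left out or a group is fitted alone.

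Fitted alone, shoot at 3 h gave 5365 calls, shoot 6 h against 3 h 0 (limma; 3942 at an unadjusted p under 0.05 in the joint fit), root 6 h against 3 h 8, and the same direction in both tissues at 3 h 3730 (against 8123). Agilent's processed signals and the deposited table gave 2984 and 2983 at least 2-fold changes in shoot at 3 h, 9971 and 9966 in root at 6 h, 28 and 32 calls for shoot 6 h against 3 h, 104 and 106 for root, and 6825 each at 24 h in shoot. Scaling between arrays gave 3119 (shoot, 3 h) and 4559 (root, 3 h) at least 2-fold changes, 6 calls for root 6 h against 3 h and 5165 at 24 h in shoot. No background correction gave 4316 there, and median centring 7318, with 36 calls for shoot 6 h against 3 h; the strict filter on dim probes gave 17 and the trend and robust prior 59.

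For 6 h against 3 h, the replicate block gave 791 calls in shoot and 2270 in root and moved no other count past 1.5 times; slide as a random block gave 1025 and 1493, the block within each tissue 2808 and 4842, and slide as a fixed block 353 and 955. Without the slide 2 arrays root gave 44. With the replicate block all 140 and all 243 calls were kept, with the fixed slide block 115 and 218.

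Leaving out 1 replicate, with no block in the fit, gave 7565 to 11697 calls in shoot at 3 h and 4 to 10 for shoot 6 h against 3 h. It gave 0 (limma, without replicate 1 or 3, against 5191 at an unadjusted p under 0.05 with all) to 219 for root 6 h against 3 h, and 9236 to 14294 for root against shoot at 6 h. The same direction in both tissues was called for 5055 to 7393 probes at 3 h and 6461 to 8799 at 6 h.

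With Agilent's signals the majority of calls turned from higher to lower in shoot at 3 h and 6 h (44.7% and 48.7% higher), root at 3 h and 6 h (43.5% and 47.4%; 47.7% of at least 2-fold changes at 6 h) and root against shoot (47.0% and 46.5%), and likewise with the deposited table. For root against shoot at 6 h, at 50.6%, it also turned with the strict filter (48.1%), without replicate 2 (49.3%) and, barely, with scaling between arrays. The share of higher calls moved by over 10 points with median centring for at least 2-fold changes at 6 h (shoot 70.6% against 58.8%, root 65.6% against 53.9%) and root 6 h against 3 h (64.6% against 25.9%), and with Agilent's signals and the deposited table for root at 3 h (52.5% each against 63.8%). For shoot 6 h against 3 h it was 78.6%, 71.9%, 64.7% and 52.8% with Agilent's signals, the deposited table, the strict filter and median centring, against 49 of 140, and 47.7%, 45.3% and 45.4% with the replicate block, slide as a random block and the block within each tissue, and 23.7% with the trend and robust prior; for root it was 36.5% with Agilent's signals and 0% with scaling between arrays or fitted alone.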

Other observations

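The tests chosen after the data were seen are the motif reading and the 0 h comparison: the motifs were narrowed once their matches among the probe sequences were known, before those probes' ratios were read, and the limits of the 0 h comparison were set with the data at hand.

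A few probes could be read as protein, because their 60 bases translate into a short motif known from textbooks, with 0 matches on the reverse strand for each motif; this is a reading of the sequence, not an annotation. Hv2121F15_1 encodes a dehydrin K-segment (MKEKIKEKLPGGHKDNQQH), a motif of proteins that accumulate in drying plant tissue, and rose in all 4 groups by limma, by 1.15 ± 0.60 and 1.22 ± 0.20 in shoot at 3 h and 6 h and by 3.15 ± 0.93 and 2.95 ± 0.41 in root (SD, n = 4). Its rise was larger in root at both times (limma adjusted p = 0.00128 and 0.00333), and it read 0.52 in shoot and 4.47 in root at 24 h. Hv3026O14_1, with the end motif of cytosolic HSP70 and HSP90 chaperones, rose by 1.56, 2.15, 2.11 and 2.80 in shoot at 3 h and 6 h and root at 3 h and 6 h. Hv1041G02_1, with a motif of protein phosphatases 2C, rose in root at 3 h (1.99 ± 1.30, limma adjusted p = 0.00926) and did not pass in the other groups. Hv3124H05_1, with a class III peroxidase motif, fell in all 4 groups, by -1.24, -1.93, -0.78 and -0.50, and Hv3087P11_1, with an actin end motif, fell in shoot at 6 h (-0.66) and in root (-1.24 and -1.40). Hv2042L17_1, the other actin probe, fell in all 4 groups, by -0.56, -0.73, -0.41 and -0.53. Hv1032E14_1, with a thioredoxin active site, rose in shoot (0.76) and root (0.58) at 3 h and did not pass at 6 h, and Hv3090H24_1, with an EF-hand, rose in root (0.26 and 0.24), with no called difference from shoot (limma adjusted p = 0.503 and 0.459). Hv2008N20_1, the other peroxidase probe, read 0.08, 0.05, 0.23 and 0.21 and did not pass in any group. Hv3077I13_1, with the basic region of group A bZIP factors, which act in ABA signalling, read between -0.25 and -0.07 and passed in root at 3 h (-0.25, limma adjusted p = 0.0395).

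Before treatment, shoot and root differed in many probes. Of 38065 probes compared in Cy3 by limma (n = 4 per tissue, each the mean of the 3 h and 6 h arrays of one replicate number), 27885 were called, 17961 higher in root and 9924 higher in shoot. The 1000 probes highest in shoot over root, chosen on 2 replicates and read on the other 2, had median log2 ratios of -0.42 and -0.28 in shoot at 6 h, with the choice made on replicates 1 and 2 or on 3 and 4. At 3 h in shoot the medians were -0.11 and -0.05, and in root -0.09 and -0.29 at 3 h and -0.26 and -0.15 at 6 h. Over all compared probes the medians of the groups lay between -0.0085 and 0.0155. The 1000 highest in root had medians of 0.15 and 0.13 in shoot at 3 h, 0.11 and 0.10 at 6 h, and in root -0.01 and -0.05 at 3 h and -0.26 and -0.13 at 6 h. Probes needed a Cy3 signal well above background on at least 8 arrays, which 1 tissue alone can supply. Ratios in the tissue with the lower level may therefore lie near background.

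At 24 h, at least 2-fold ratios that were within 0.5 of 0 on the replicate 1 arrays at 3 h and 6 h were found for 296 probes in shoot, 139 of them higher, and for 673 in root, 259 of them higher. The arrays of replicate 1 at 3 h and 6 h had 4855 and 4878 probes with at least 2-fold ratios in shoot and 9350 and 6249 in root. With 1 array per time these values have no test.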
